A study of Lactiplantibacillus plantarum with 4 samples.

How the data were processed

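The 4 RNA samples came from Lactiplantibacillus plantarum WCFS1 and were compared on 4 two-colour arrays. Per the labels, cultures were grown in CDM or MRS, RNA was extracted with phenol and chloroform, mRNA was enriched, and total RNA and enriched mRNA were reverse transcribed from a T16N2 primer with dye-labelled nucleotides. Arrays compared MRS enriched mRNA (Cy5) with MRS total RNA (Cy3), CDM enriched with MRS enriched, CDM total with CDM enriched, and MRS total with CDM total, the Cy5 sample named first. Dyes were taken from the labels. How enrichment was done is not given in the sources used here.

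Each deposited array file gives, per the file headers, the mean signal intensity, the mean local background intensity and a flag code for each spot and dye. These intensities are not background-subtracted, and the scanner and image software are not given in the sources used here. The flag codes 0, 2 and 3 are not explained. Spots with code 2 had a signal close to their background, and code 2 was read as dim; it covered 16.7 to 28.8% of probes per channel. The deposited value table of the series holds the authors' processed ratio for each spot. Set against the array files, it is Cy5 over Cy3 on a linear scale after background subtraction and an intensity-dependent correction, with medians of 0.95, 0.97, 1.03 and 1.02 in the array order above. Its log2 values correlated at 0.95 to 0.99 with the background-subtracted log2 ratios of the same spots. It is empty where a background-subtracted signal was not above 0, which was 398 to 535 spots per array. The scale and direction were settled in this way, and the exact centring rule stays unknown.

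Signals were corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 (R 4.3.3), with control spots at weight 0. Normexp fitted a lower mean on the array of MRS enriched against MRS total (-559 in Cy5 and -629 in Cy3) than on the other arrays (-323 to -162), which compresses the ratios of dim spots there. A total of 814 probes with code 2 in both dyes on all 4 arrays were left out, leaving 8358 probes of 2982 tags; 111 tags had no probe left. Log2 ratios were averaged over the probes of a tag, of which 2568 tags had 3, 240 had 2 and 174 had 1. The 60 control spots were left out, as were 39 probes named mtf or antilp, which appear only in the closing section.

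The log2 ratios were fitted with lmFit and eBayes, with terms for medium (CDM minus MRS), RNA type (enriched minus total) and dye. Each coefficient of medium or RNA type is the mean of 2 arrays of opposite dye orientation that share no RNA sample. The fit has 1 residual degree of freedom, which holds the interaction and noise, and 6.3 prior degrees of freedom. Tags with a Benjamini-Hochberg adjusted p under 0.05 counted as changed. The dye term called 0 tags in limma, with 228 at an unadjusted p under 0.05. Data were simulated for the 2982 tags, with noise drawn from the variance prior of the same fit. They held no interaction and fewer changed tags than were called on the arrays, so rates from them may not carry over. The script was tested on these simulated data. For the medium comparison it recovered 0% of changes of 0.5 on the log2 scale, 48.3% of 1 and 96.8% of 2, and for RNA type 1.6%, 37.5% and 93.8%; unchanged tags made up 2.2% of the calls in each.

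Tags were named by a rule fixed before the data were examined. It takes the largest rises and falls among tags past the threshold with an absolute log2 change of at least 1 and the same direction on both direct arrays. The first 2 of each are printed, since the files pair no names with the tags. For a named tag near background in a sample of its lower group, a second fold is given beside the fitted one. It compares means of log2 channel levels after loess and Aquantile scaling, in which a dim level counts as no lower than the lowest signal not coded 2. Every sample of the lower group was dim for 24 of the 860 tags changed between media and 19 of the 472 changed between RNA types. Of 29 gene lists fixed by symbol or product, 28 could not be filled, since 0 tags matched the reference table of assembly ASM991365v1. The list of ribosomal and transfer RNA was filled in part by the 14 tags whose names spell tRNA. The p1 to p3 series was tested in place of a list of plasmid genes, a choice made after the names were seen; whether these tags lie on plasmids is not stated in the files. Lists were tested with limma's camera (preset correlation 0.01) and against 10000 random lists matched on intensity. Runs of neighbours used 2923 tags in number order and no coordinates.

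Alternatives fixed before the data were examined were no background correction, median centring, scaling between arrays, the authors' values, no filter or the brighter 75% of tags, no dye term, medians over probes, a test per probe, a trended and robust prior, a fold rule and leaving out each array. The 3 arrays left then cannot hold the dye term, so these fits leave it out too. Added after seeing the data were leaving out spots of code 3, plain background subtraction, leaving out the tRNA tags, further settings for the lists, and the counts of tags in runs. Figures were drawn with matplotlib 3.10.9.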

Results

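Transcript levels were measured in Lactiplantibacillus plantarum WCFS1, a lactic acid bacterium, with 4 two-colour DNA microarrays. The 4 RNA samples compared were total RNA and enriched mRNA from cells grown in MRS, a rich medium for lactobacilli, and the same pair from cells grown in CDM, as the labels call the other medium. The samples formed a loop of 4 arrays in which each RNA sample was labelled with Cy5 on 1 array and with Cy3 on another. Each array held 9271 spots, of which 9172 were probes for 3093 locus tags. A locus tag is the serial name of an annotated gene. The median probe signal was between 4.01 and 6.94 times its local background over the 8 channels, and 4 arrays limit the precision of every value. The labels name no number of cultures, and each of the 4 RNA samples was its own condition, so p-values hold no spread between cultures. They rest on how far the 4 arrays depart from a fit that is additive in medium, RNA type and dye, with a variance prior shared by all tags. The part of a difference between the 2 direct arrays of an effect that the dye term takes up does not enter its SE or p. Such differences are thus treated as dye bias, although their cause stays open (see other observations). The files hold locus tags without gene names, and none of the tags was found in the reference gene table, which describes another strain. Tags are therefore named by their identifiers, and at most 2 that rose and 2 that fell are named per comparison.

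The first comparison asked which transcripts differed between growth in CDM and in MRS. Of the 2982 tags tested, 495 were higher and 365 were lower in CDM, 28.8% of all tags together (limma loop fit, Benjamini-Hochberg adjustment). At least 2-fold changes made up 205 of the rises and 103 of the falls, and at least 8-fold changes made up 25 and 12. Among the rises, lp_2034 had a fitted effect of 4.86 ± 0.19 on the log2 scale (SE, 4 arrays), or 29.0-fold, with a limma adjusted p of 6.3e-06. The tag lp_3271 had 4.72 ± 0.21 (26.4-fold, limma adjusted p = 8.8e-06). Their order is not fixed, since with no background correction lp_2034 was at 3.70 and lp_3271 at 4.17. Among the falls, lp_3049 had a fitted effect of -4.82 ± 0.19, or 28.2-fold lower in CDM (limma adjusted p = 6.3e-06), and lp_0256 one of -4.43 ± 0.18, or 21.6-fold lower (limma adjusted p = 6.3e-06). All probes of lp_3049 were near background in 1 of the 2 CDM samples, and channel levels after quantile scaling of the mean intensities gave 21.3-fold for it and 21.9-fold for lp_0256, so their order is not fixed. Each of these 4 tags had 3 probes and, as the naming rule required, the same direction in enriched mRNA and in total RNA. Over the alternatives lp_2034 lay between 3.70 and 6.19, lp_3271 between 4.12 and 5.07, lp_3049 between -5.95 and -3.90, and lp_0256 between -4.75 and -3.92. The values of lp_3271 and lp_0256 rest on spots of the unexplained flag code 3, without which at least 1 array had no value for them. Their levels in the higher group (mean log2 of 15.17 in CDM and 15.20 in MRS) were close to the highest signals, so these folds may be understated.

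Tags that differed between the media lay in groups of neighbours. Tag numbers were taken to follow the order of the genes, and 2923 of the tested tags carry a plain number. Among them, 362 of the 850 that passed the threshold, or 42.6%, stood in runs of at least 3 consecutive tags changed in 1 direction. Of these 85 runs, 50 were higher and 35 lower in CDM. The higher runs include lp_1261 to lp_1265, where the arrays disagreed on the same RNA sample (see other observations). In 10000 shuffles of the tag order the median was 51 tags in runs and the maximum 104 (permutation p = 1e-04, the smallest these shuffles can give). The tag lp_2034 stood in a run of 6 tags with a median of 4.33 (20.2-fold), and lp_3271 in a run of 4 with a median of 3.79 (13.8-fold). The tag lp_0256 closed a run of 3 with a median of -4.11 (17.3-fold lower), while both neighbours of lp_3049 missed the threshold. The longest run held 12 tags higher in CDM with a median of 2.96 (7.80-fold), and the next held 11 with a median of 1.81 (3.50-fold). This grouping was looked for after the data were seen.

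**Figure D1:**
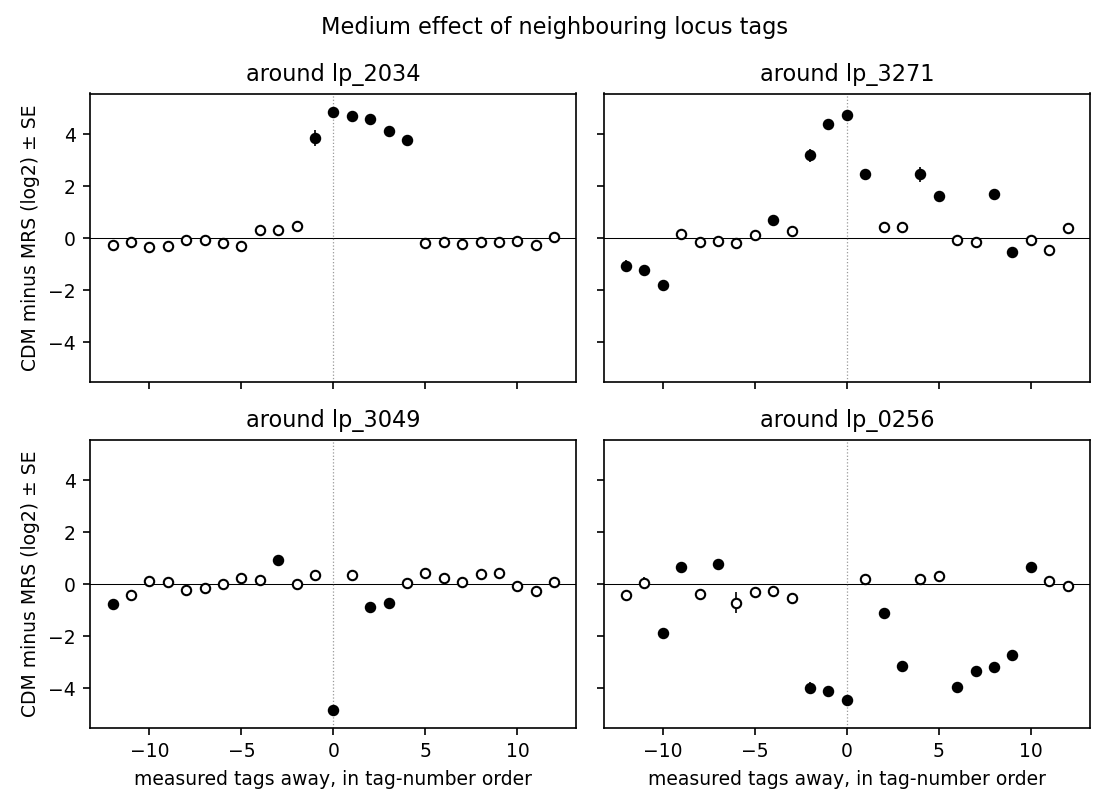
Medium effect (CDM minus MRS, log2, with SE from the limma loop fit of 4 arrays) of the 12 measured tags on either side of the 4 named tags, in tag-number order. Filled points passed the threshold and open points did not; lp_2034 sits in a run of 6 tags and lp_3049 stands alone.

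The medium effect was measured on an array of enriched mRNA and on an array of total RNA that shared no RNA sample. The labels do not say whether the total and the enriched RNA of a medium came from 1 culture, so both arrays may compare the same cultures. Across the 2982 tags, which are not independent replicates, the 2 arrays correlated with a Pearson r of 0.81 and a Spearman rho of 0.73. The sign was the same on both for 2321 of all 2982 tags (77.8%) and for 858 of the 860 past the threshold, which were selected on the mean of these arrays. The SD of the effect over tags was 0.88 in enriched mRNA and 0.76 in total RNA, and the SD of the difference between the arrays was 0.51. The count of changed tags fell to 446 when spots with flag code 3 were left out; fits with an array left out hold no dye term, and called 245 without the array of enriched mRNA and 439 without that of total RNA, against 757 with all arrays and no dye term. With a medium array left out, the effect is the value of the other medium array and its error comes from the RNA type arrays. Those counts therefore do not measure how well the effect repeats. The count of changed tags was 473 with the authors' values, 504 with plain background subtraction, 460 after scaling between arrays, 240 on a fold rule, and 1318 probes in a test per probe.

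**Figure D2:**
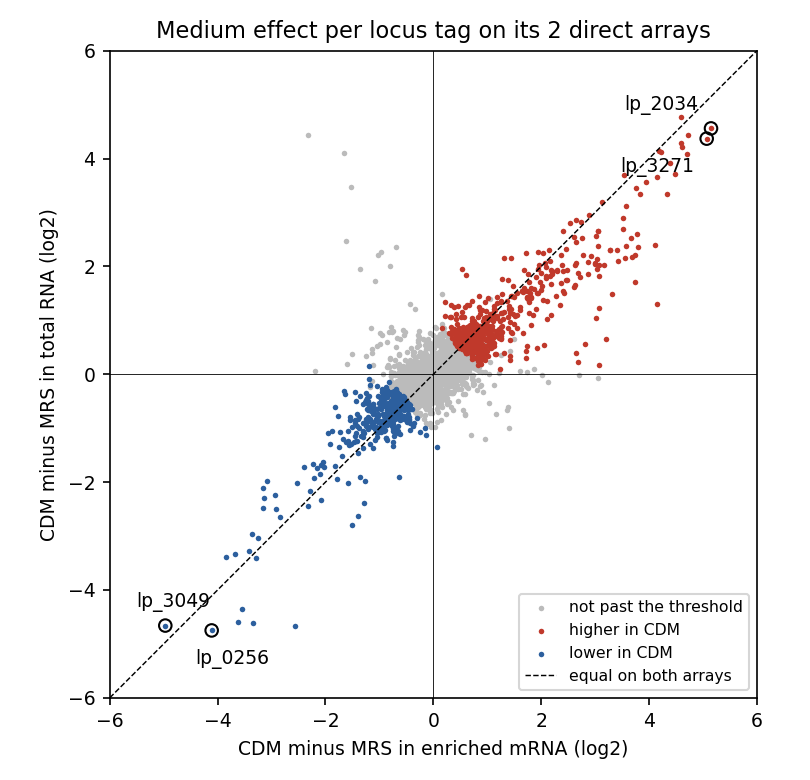
Medium effect (CDM minus MRS, log2) of each of the 2982 tested tags on the array of enriched mRNA (horizontal axis) and of total RNA (vertical axis). Red and blue points passed the limma threshold, circles mark the 4 named tags, and 77.8% of all tags have the same sign on both arrays.

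The second comparison asked how the profile of enriched mRNA differed from that of total RNA. Relative signal was higher in enriched mRNA for 326 tags and lower for 146, 15.8% of the 2982 tested together (limma loop fit, Benjamini-Hochberg adjustment). At least 2-fold changes made up 129 of the rises and 44 of the falls, and 3 rises and 0 falls were at least 8-fold. Among the rises, lp_tRNA50, a tag whose name spells a transfer RNA, had a fitted effect of 3.76 ± 0.43 (SE, 4 arrays), or 13.5-fold, with a limma adjusted p of 0.0022. It measured 4.89 in MRS and 2.62 in CDM, and missed the threshold without the CDM array and the dye term (adjusted p = 0.052) and with the authors' values (0.053, the highest of its alternatives). The tag lp_1637 was at 3.23 ± 0.21 (9.40-fold, limma adjusted p = 7e-04), with 4.02 in MRS and 2.44 in CDM. It also missed the threshold without the CDM array and the dye term (adjusted p = 0.052, the highest of its alternatives). Both tags rest on spots of flag code 3, without which at least 1 array had no value for them. Their levels in enriched mRNA (mean log2 of 15.36 for lp_tRNA50 and 15.47 for lp_1637) were close to the highest signals, so these folds may be understated. Among the falls, the naming rule took lp_2461 first, which had 1 probe kept and was near background in both enriched samples. Its fitted effect was -2.34 ± 0.39 (SE, 4 arrays), or 5.06-fold lower (limma adjusted p = 0.0089), with -1.41 in MRS and -3.26 in CDM. Its channel levels gave 5.95-fold, and since the lower level is near background neither fold is firm. The tag lp_0247 fell by 2.08 (SE 0.41, 4 arrays), or 4.23-fold (limma adjusted p = 0.015). With the dim probes of lp_2461 included its effect was -0.69, and lp_2461 and lp_0247 missed the threshold under 4 and 8 of 15 alternatives each. Among these alternatives, leaving out either medium array gives the same fit for RNA type. Tags past this threshold formed 6 runs of neighbours with 20 tags (permutation p = 0.07 over 10000 shuffles).

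Transfer RNA tags were higher in enriched mRNA as a group. Of the 14 measured, 10 rose, 0 fell and 4 did not pass the threshold. Adjusted over the list alone, 11 rose. Their median was 1.67 (3.18-fold), and single tags lay between -0.18 and 3.76. The medians were 1.72 on the MRS array and 1.78 on the CDM array, and 12 of the 14 tags were above 0 on both. These near-equal medians hide differences in single tags. Most tags, like lp_tRNA50, were higher on the MRS array. The tags higher on the CDM array lay below the median intensity of the list (12.89), at -0.18 to 2.07 in MRS and 1.70 to 2.68 in CDM. These differences hold the dye term and were not tested. Against the other tags the list stood higher in limma's camera test (adjusted p = 9.7e-09 at a preset correlation). Its median lay above all 10000 random lists matched on intensity. These lists were not matched on the number of probes, and each tRNA tag had only 1 or 2 kept, while 2568 of the 2982 tags had 3. The call was lost with an estimated correlation (camera adjusted p = 0.32). That form of the test rests on the 1 residual degree of freedom of the fit, so it could hardly pass and decides nothing here. The preset p in turn rests on the assumed correlation. In the medium comparison 2 of the 14 tags rose, by 3.25 and 1.25, and 1 fell by 0.69, with a list median of -0.08 (camera adjusted p = 0.95, and adjusted p = 0.97 with an estimated correlation). Counts adjusted over the list alone were also 2 and 1.

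**Figure D3:**
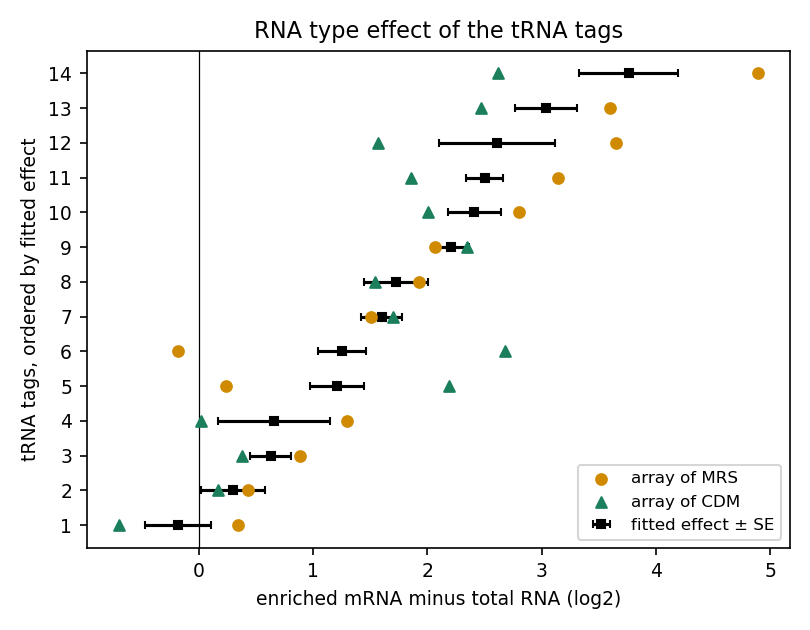
Enriched mRNA minus total RNA (log2) of the 14 tRNA tags, ordered by the fitted effect. Squares with bars are the limma estimate ± SE from 4 arrays, circles the array of MRS and triangles the array of CDM; 12 of the 14 tags lie above 0 on both arrays.

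A second group was defined by tags whose names carry p1, p2 or p3 in place of a plain number. Of its 42 measured tags, 2 rose and 4 fell in enriched mRNA, and adjusted over the list alone 2 rose and 3 fell. The list median was -0.17, below all but 0.07% of random lists (camera adjusted p = 0.0046). With an estimated correlation the call was lost (camera adjusted p = 0.36), again on 1 residual degree of freedom, where the test could hardly pass. Between the media, 1 of the 42 tags was higher and 6 were lower in CDM, and adjusted over the list alone 1 and 3. All 6 of the lower tags belonged to the 38 of the p3 series. The median of the group was 0.02, and camera gave adjusted p = 0.95 (adjusted p = 0.97 with an estimated correlation). The 2 tags whose names spell only RNA were among the brightest on the arrays, with mean log2 intensities of 15.48 and 15.29. Neither passed the threshold for RNA type, with effects of 0.09 ± 0.15 and 0.78 ± 0.24 (SE, 4 arrays; limma adjusted p = 0.76 and 0.071). At this brightness, close to the highest signals on the arrays, a change may go unseen. The tag named SRP did not pass either, at 0.20 ± 0.16 (SE, 4 arrays; limma adjusted p = 0.45).

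The RNA type effect was likewise measured on 2 arrays, of MRS and of CDM. Across the tags, which are not independent replicates, enriched minus total in MRS correlated with the same difference in CDM at a Pearson r of 0.67 and a Spearman rho of 0.64. The SD of the difference between these arrays was 0.44, against 0.51 for the medium arrays, and the SD of the fitted effect over tags was 0.49, against 0.78 for the medium. The sign was the same in both media for 2145 of all 2982 tags (71.9%) and for 469 of the 472 past the threshold, which were selected on the mean of these arrays. The probes of a tag also differed more in this comparison, with an intraclass correlation of 0.46 against 0.90 for the medium effect. Without the dye term the count of changed tags was 310 with all arrays, 51 without the MRS array, 0 without the CDM array and 265 with either of the 2 medium arrays left out. Without the MRS or the CDM array the effect is the value of 1 array and its error comes from the medium arrays. Those counts therefore do not measure how well the effect repeats. Leaving out either medium array gives the same fit for RNA type. With the dye term the count was 37 without spots of flag code 3, 178 with the authors' values, 243 with plain background subtraction, 890 with no background correction, 258 with medians over probes, 756 with a trended robust prior and 92 on a fold rule.

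Whether the medium effect itself depended on the RNA type was not tested in the loop with a dye term, which leaves no degree of freedom for it, and was tested only in a fit without that term. The difference was taken from a saturated fit of all 4 arrays, in which the dye term cancels. It was at least 1 in absolute log2 size for 41 tags, 19 with a higher value in enriched mRNA and 22 with a higher value in total RNA. The 2 medium arrays alone, with the dye term not removed, differed by at least 1 for 123 tags, 69 and 54 in these directions. The limma fit without the dye term called 0 tags after Benjamini-Hochberg adjustment and 106 at an unadjusted p under 0.05. The largest fitted difference was that of lp_1088, singled out after its values were seen. This tag measured 2.71 between the media in enriched mRNA and -0.01 in total RNA, with a fitted difference of 2.96 ± 0.22 (SE, 4 arrays; limma adjusted p = 0.11).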

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

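None of the differences between arrays in this part was tested or freed of the dye term, and the comparison of other probes with control spots was chosen after the data were seen. The tRNA tags had a median medium effect of 0.47 in total RNA and -0.47 in enriched mRNA, so the 2 arrays had opposite signs. Among random lists matched on intensity these medians were at percentiles 99.58 and 0.39. The tags of the p1 to p3 series had medians of 0.05 in total RNA and -0.03 in enriched mRNA. Of the 2 tags whose names spell only RNA, 1 measured 0.30 for enriched minus total in MRS and -0.12 in CDM. The other measured 1.58 in MRS and -0.03 in CDM. Between the media, 8 tags were at least 2-fold changed in opposite directions on the array of enriched mRNA and the array of total RNA. Between RNA types, 2 tags were at least 2-fold changed in opposite directions in MRS and in CDM.

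Probes named mtf, which belong to no locus tag and to no comparison above, gave signal above the control spots. Of the 18 forward probes, 16 had a mean log2 signal over background higher than the brightest of 60 control spots, which reached 1.23. Of the 18 probes whose names add rev, 13 did. The medians were 2.76 for the forward and 2.43 for the rev probes, against -0.03 for the control spots. The median medium effects of the forward and rev probes were 0.07 and 0.21 and their median RNA type effects 0.16 and 0.31, with no test. The 3 antilp probes had a median of 0.22 and none was above the brightest control spot. What these names stand for is not stated in the files.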

How the results depend on the processing

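The tests per list beyond those named in the methods, the runs of neighbours, plain background subtraction and leaving out spots of code 3 were chosen after the data were seen. Of 117 recalculated values of the 8 named tags, 0 changed sign. Many could not, as they repeat the fitted effect or 1 direct array, whose sign the naming rule fixed. Of the 117, 102 stayed past the threshold and 15 lost it. These counts take as separate the fits that leave out either array of the other effect, which are the same fit. The 4 tags of the medium comparison lost it in none, with adjusted p up to 0.012. The tag lp_0247 lost it in 8 of 15 (adjusted p up to 0.42), lp_2461 in 4 of 15 (up to 0.15), lp_tRNA50 in 2 of 14 (up to 0.053) and lp_1637 in 1 of 15 (0.052). No value was possible without spots of code 3 for lp_3271, lp_0256, lp_tRNA50 and lp_1637, whose higher groups were the brightest of the 8 tags (mean log2 levels of 15.17 to 15.47, against at most 13.86), nor among the brighter 75% of tags for lp_2461 and lp_0247.

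Counts of changed tags moved by over 1.5 times from 860 between media to 460 with scaling between arrays, 473 with the authors' values, 446 without code 3 spots, 504 with plain subtraction, 240 on the fold rule and 1318 per probe, and lay between 245 and 633 with 1 array left out. From 472 between RNA types they moved to 890 with no background correction, 178 with the authors' values, 310 without the dye term, 258 with medians over probes, 756 with the trended robust prior, 37 without code 3 spots, 243 with plain subtraction and 92 on the fold rule, and lay between 0 and 265 with 1 array left out. Fits with 1 array left out also hold no dye term, and compare with 757 and 310 from all arrays without it. Leaving out code 3 spots left values for 731 of the 860 and 346 of the 472 tags. The cause of these moves was not tested. All 860 and 472 changed tags kept their sign after median centring.

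Called tags in runs numbered 362, and 576 with no background correction, 173 with scaling, 175 with the authors' values, 154 without code 3 spots, 183 with plain subtraction and 91 to 255 with 1 array left out (282 from all arrays without the dye term), while the correlation between adjacent tags lay between 0.48 and 0.52. The correlation between the media arrays was 0.81, and 0.86 with no background correction, 0.75 with median centring, 0.74 with the authors' values, 0.90 among brighter tags and 0.75 with plain subtraction. For RNA type it was 0.67, and 0.79, 0.49, 0.58, 0.78 and 0.59 in the same order. Both were higher among brighter tags than over all tags, where the signal lay further above background. The 41 tags with an interaction of at least 1 compare with 0 past the threshold without the dye term.

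The tRNA median for RNA type lay between 1.55 and 2.60, and its camera call was lost only with an estimated correlation (adjusted p = 0.32), as was that of the p1 to p3 series (adjusted p = 0.36); under the other settings the adjusted p was at most 1.3e-05 and 0.026. The test with an estimated correlation has only 1 residual degree of freedom, so it could hardly pass and decides nothing on either list. Neither list passed a test between media. There the tRNA median of -0.08 ran from -0.47 to 0.47 with 1 array left out, and the p1 to p3 median of 0.02 from -0.03 to 0.05, and was -0.01 with the authors' values.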

Other observations

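Of the explanations weighed here, those on dye bias and on different RNA behind the 2 targets of a sample were tested only after the results were seen. Neighbouring tags also shared differences that the additive fit leaves out. The values of the medium by RNA type interaction correlated at 0.20 between adjacent tags, above all of 1000 shuffled orders (highest 0.06). The clearest case was the run of 4 tags that holds lp_1088. These tags had a median medium effect of 2.42 in enriched mRNA and -0.04 in total RNA, and a median RNA type effect of 1.85 in CDM and 0.00 in MRS. Their signal was thus high in the enriched mRNA from CDM, on both arrays and with both dyes, and not in the other 3 samples.

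The rise of tRNA tags in enriched mRNA, a step meant to favour mRNA, was set against 3 technical explanations. Under no background correction, median centring or the authors' values the lowest list median was 1.55. This argues against normexp or loess, each taken alone, as the whole cause. No setting left out both background correction and intensity-dependent normalization, so the 2 together were not tested. The median stood at percentile 100 among random lists matched on intensity, which argues against probe brightness. The lower of the percentiles on the MRS and the CDM arrays was also 100, so the rise was in both enriched preparations. What in the enrichment or the labelling goes with the rise stays open and was not tested. The camera call was lost with an estimated correlation (adjusted p = 0.32), a test that 1 residual degree of freedom leaves unable to decide.

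The 4 log2 ratios around the loop add to 0 if both targets of each sample are alike and the dyes act alike. For 63 tags the sum was at least 2 in absolute size, and 21 of them stood in 7 runs of at least 2 neighbours, the longest of 6 tags with a median of -3.81. Another of these runs, lp_1261 to lp_1265, was counted above as 5 tags higher in CDM (median 2.73). For lp_1261 the Cy5 minus Cy3 difference was 3.56 in enriched mRNA from MRS, and -0.22 to 0.70 in the other samples. The sum is 4 times the dye term of the limma fit, which called 0 tags after Benjamini-Hochberg adjustment. Dye bias tied to single probes would not be shared by neighbours. Shuffled orders do not cover a bias that follows intensity or sequence shared by neighbours, so dye bias was not excluded. The sums of adjacent tags correlated at 0.26, against at most 0.07 in 1000 shuffled orders. Among the brighter tags the correlation was 0.24 (highest shuffled 0.08), which argues against dim signals as the whole cause, although the 63 tags were dimmer than all tags (median log2 intensity 10.7 against 12.5). It may be that the Cy5 and the Cy3 target of enriched mRNA from MRS came from different RNA, since their difference correlated at 0.25 with the medium effect on the total RNA array, which shares no target with them. For the other 3 samples the matching values were -0.12, -0.03 and 0.13. That explanation does not cover the whole pattern, since these differences correlated between adjacent tags at 0.21 for enriched mRNA from MRS and at 0.26 for total RNA from CDM.

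A faster or slower culture could change gene dosage along the chromosome, so the medium effect was set against the distance of each tag from the middle of the tag order. The Spearman correlation was 0.039, inside the central 95% of 10000 circular shifts (-0.041 to 0.041). A gradient of that kind was thus not detected, with tag order as the only measure of position. Circular shifts keep a smooth gradient whole, so a gradient would itself widen these limits, and 0.039 lay close to the upper one. The shifts therefore cannot decide the question, and the value shows only that the correlation was weak.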
